A study of Mus musculus with 4 samples.

How the data were processed

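Gene expression was measured on Affymetrix mouse arrays in KSL cells, the Kit-positive, Sca-1-positive and lineage-negative fraction of bone marrow that holds hematopoietic stem and early progenitor cells. Per the labels, the cells came from the marrow of recipient mice transplanted with fetal liver cells that were either wild-type or Fus-null, and total RNA extracted with Trizol was turned into biotin-labelled cRNA. The labels put 2 arrays in each genotype. Nothing in the labels says that the arrays of a genotype came from separate animals. The p-values of single probe sets rest on the spread between these arrays, which may be technical, and on that of other probe sets. The main p-values of gene lists and those of Fisher tests treat genes as units and do not measure a spread between animals.

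The values deposited by the authors were intensities on a linear scale, made with MAS5, per the submitters' processing notes. The mean of the values between the 2nd and 98th percentile was 100 on every array, so the arrays had been scaled to one trimmed mean. Detection calls, other steps and software versions are not given in the sources used here. The median signal was 11.6 and 11.3 on the wild-type arrays and 11.5 and 13.6 on the Fus-null arrays, and between 31.7% and 32.2% of probe sets had a signal above 50. The number of arrays limits the precision of every value.

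The array held 45037 probe sets besides 64 control probe sets, which were left out. In the platform annotation used here 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none. Symbols were updated through the Entrez identifier with a RefSeq gene table of the mouse assembly GRCm38.p6, which was used only for names, chromosomes and the order of neighbouring genes. No gene was named from a probe set with several symbols. No probe set carried the symbol Fus, Ly6a or Ddx3y in this annotation, so these transcripts were not analysed here by name. Probe sets without a symbol were tested and may include them. The genotype labels were not checked against the Fus transcript.

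Signals were transformed as log2(signal + 2), the pseudocount being the 20th percentile of all values rounded to a whole number. A log2 difference is therefore on the log2(signal + 2) scale and understates the change of low genes. Probe sets with a mean above the 40th percentile were tested, which left 27022 probe sets with a mean signal of at least 5.99. Of these 22617 had 1 symbol and stood for 12308 genes. Fus-null was compared with wild-type with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, 2 residual and 5.83 prior degrees of freedom), all tests being two-sided unless stated, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. A second, untested count took the probe sets that differed by at least 1 on the log2 scale in the same direction in all 4 pairs of a Fus-null and a wild-type array. An exact permutation test of 2 arrays against 2 cannot go below a two-sided p of 0.333, so none was used.

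Gene lists were written from textbook knowledge of stem and progenitor cells, of the mature cells that the KSL gate removes, and of processes linked with Fus. There were 32 lists with 1125 entries, of which 979 had a named probe set. Each gene was represented by its brightest probe set. The 31 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, with adjustment over the lists. For each list the members past the threshold were counted after adjustment over all probe sets and after adjustment over the list alone.

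The genes named are the probe sets of Fus, Ewsr1, Taf15, Kit, Ly6a, Cdkn1a and Mecom, the 12 genes with the largest rise and the 12 with the largest fall among probe sets with exactly 1 symbol past the threshold, the 3 members of each list with the largest absolute log2 difference, and the neighbours of Fus on chromosome 7 that met the 2-fold rule. Other genes are named only where stated, after their values were seen. The groups, main tests, lists, naming rule and alternative settings were fixed before the data were examined. The exceptions are 3 settings, and further tests such as the Fisher tests, identified as added later. The alternatives were other pseudocounts, filters, normalizations and variance models, a fit with the replicate number as a block, other ways to test a list, and leaving out each array in turn.

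The procedure was tested on simulated data with 27022 probe sets, of which 200 were changed. For this comparison it recovered 33% of changes of 1 and 76% of changes of 2 on the log2 scale, with 7.63% false calls among 118, and 62 unchanged probe sets met the 2-fold rule. With no list shifted it called 0 lists. The simulated noise was independent between probe sets and equally wide in both groups. It therefore cannot give the rate of false calls for lists whose genes vary together. On the real arrays the replicate differences had an SD of 0.369 in wild-type and 0.503 in Fus-null cells on the log2 scale. The simulated rates for single probe sets may thus differ from the real ones too.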

Results

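Transcripts of KSL cells were compared between 2 Fus-null and 2 wild-type arrays. Fus encodes an RNA- and DNA-binding protein of the FET family, and the comparison asks which transcripts differ with its loss in stem and progenitor cells that have repopulated a recipient. Across tested probe sets the log2 signals of the wild-type arrays correlated at 0.987, those of the Fus-null arrays at 0.975, and those of arrays of different genotype at 0.966 to 0.978.

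Klf2, Nr4a3, Fosl1 and Hspa1b fell in the Fus-null cells, and Car1 rose. Klf2, a transcription factor of quiescent blood cells, went from a signal of 1768 ± 4.63 (SD, n = 2) in wild-type to 544 ± 30.9 (n = 2), a log2 difference of -1.70 (SE 0.11, limma adjusted p = 0.000941). Nr4a3, an orphan nuclear receptor of the immediate-early class, fell from 104 ± 11.1 to 17.8 ± 0.932, and Fosl1, a Fos-family subunit of AP-1, from 46.0 ± 4.65 to 12.6 ± 1.74, though Fosl1 did not pass with no filter (adjusted p = 0.0939 by limma) or without wild-type replicate 1 or 2 (0.145 and 0.0954). Hspa1b, an inducible heat-shock chaperone, fell by 1.66 on the log2 scale at its most changed probe set, and its 2 other probe sets passed as well. Car1, the carbonic anhydrase of the red cell lineage, rose from 29.8 ± 5.26 to 228 ± 0.342, a log2 difference of 2.86.

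In all, 62 probe sets rose and 110 fell at an adjusted p under 0.05 by limma, among 27022 tested. Of these 172, 139 had 1 symbol and stood for 123 genes, while 33 did not have exactly 1 symbol. At an unadjusted p under 0.05 there were 4151, where 1351 would come by chance. The same fit on the other 2 ways of splitting the 4 arrays called 0 and 1 probe sets, with 369 and 453 at an unadjusted p under 0.05. In those splits the genotype difference widens the spread within each group, which lowers the counts. They are therefore no measure of the calls expected by chance. The count depended on the variance model, since without the intensity trend 14 probe sets passed, 9 higher and 5 lower. It also depended on dim probe sets, since 78 passed with no filter, 28 higher and 50 lower. With each array scaled to its median instead, 25 rose and 80 fell. Leaving out 1 array gave 134 or 83 calls without wild-type replicate 1 or 2, and 4226 or 871 without Fus-null replicate 1 or 2, where the lone remaining array is assumed to vary like the other genotype. Of 75 probe sets past the threshold whose genes are named in these results or among the other observations, 7 passed without the intensity trend, those of Xist, Eif2s3y, Gdpd3, Gpr4 and Sec23ip, while 42 passed with no filter, 54 with median scaling, and 43 or 44 without wild-type replicate 1 or 2. Pola1, Ifit2, Hlf, Zfpm1, Csf3r, Klf9, Klf11, Mn1 and 1 probe set each of Klf6 and Nr4a2 passed in none of these settings.

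**Figure D1:**
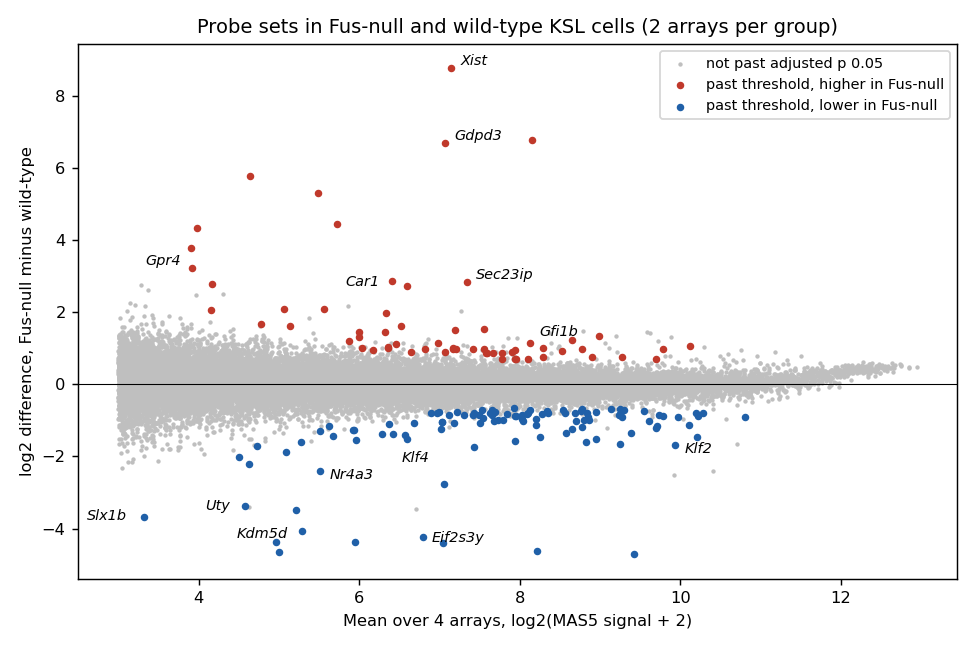
Log2 difference between Fus-null and wild-type arrays (vertical axis) against the mean log2(signal + 2) over the 4 arrays (horizontal axis) for the 27022 tested probe sets. Red points are the 62 probe sets that rose and blue points the 110 that fell at an adjusted p under 0.05, and grey points did not pass. For a gene with several probe sets past the threshold, the label marks the one with the largest difference.

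Xist, the noncoding RNA that silences an X chromosome in female cells, had the largest difference of all tested probe sets. It rose from 5.38 ± 4.02 to 2957 ± 379, a log2 difference of 8.76 (SE 0.33, limma adjusted p = 3.62e-05), and its 2 other probe sets rose by 6.76 and 5.77. The Y-linked genes Eif2s3y, a translation initiation factor subunit, Kdm5d, a histone demethylase, and Uty, a demethylase-like protein, fell, with log2 differences of -4.23, -4.07 and -3.38. Eif2s3y went from 480.4 ± 44.4 to 23.7 ± 2.62. The other tested probe set of Uty had a log2 difference of -1.225 and did not pass (limma adjusted p = 0.17). Each of the 4 arrays fell on the side of its genotype for these 4 genes, so every comparison of the genotypes here is also one between arrays with high Xist signal and arrays with Y-linked signal. Among the 172 probe sets, 6 that rose and 2 that fell lay on the X chromosome, and 3 that fell on the Y chromosome. On autosomes lay 38 that rose and 89 that fell, and 1 that rose had a symbol but no known chromosome. The other 33, without exactly 1 symbol, were not placed, so the X and Y counts may be too low. They include the probe set with the lowest p of all, which fell from 606 ± 16.4 to 26.6 ± 0.403 (limma adjusted p = 1.48e-05). In a setting added after the data were seen, without genes of X and Y and without unnamed probe sets, 106 probe sets passed, all of them among the 172.

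Further genes with the largest rises came from several classes. Fcer1g, the signalling chain of Fc receptors on myeloid cells, rose from 46.4 ± 3.80 to 132 ± 28.2, and Ccr9, a chemokine receptor of lymphoid precursors, from 13.4 ± 0.998 to 46.7 ± 1.44. Ermap, a membrane protein of erythroid cells, rose from 6.82 ± 1.51 to 34.4 ± 0.647. Of these, Fcer1g did not pass with median scaling, and Ccr9 and Ermap with no filter or without wild-type replicate 1. Rps4l, a gene related to a ribosomal protein, rose from 39.1 ± 6.82 to 158 ± 2.42, and the proton-sensing receptor gene Gpr4 from 2.99 ± 0.105 to 44.4 ± 7.22. The immunoglobulin kappa segment Igkv9-120 rose from 2.51 ± 2.81 to 61.3 ± 42.8, with 91.5 on 1 Fus-null array and 31.0 on the other, and its call was lost with the pseudocount at the 5th, 50th or 75th percentile, with no filter, without the intensity trend, under quantile normalization or cyclic loess, and without X, Y and unnamed probe sets. Gm10451, which did not pass with no filter, and 1500011B03Rik rose by 2.10 and 1.52 on the log2 scale. A 2nd probe set of 1500011B03Rik differed by 0.19 and did not pass. The other tested probe sets of Gm10451 and Ccr9 were also higher but did not pass.

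Among the genes with the largest falls, the immunoglobulin lambda segment Iglv1 went from 351 ± 92.1 to 49.5 ± 4.63. Its other tested probe set was also lower but did not pass. Eps8l1, related to the actin regulator Eps8, fell by 2.20 on the log2 scale and passed at both of its probe sets, though at neither with no filter or without wild-type replicate 1. H3c11, a replication-dependent histone H3 gene, fell from 63.1 ± 6.0 to 15.9 ± 2.14 and did not pass without wild-type replicate 1. Rbmx, an X-linked gene for an RNA-binding protein of the hnRNP class, fell by 1.73 at 1 probe set, which did not pass with no filter, whereas its 2 other probe sets differed by 0.08 and 0.07 and did not pass. Among the probe sets past the threshold without exactly 1 symbol, the largest fall was a log2 difference of -4.72 and the largest rise one of 5.30.

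**Figure D2:**
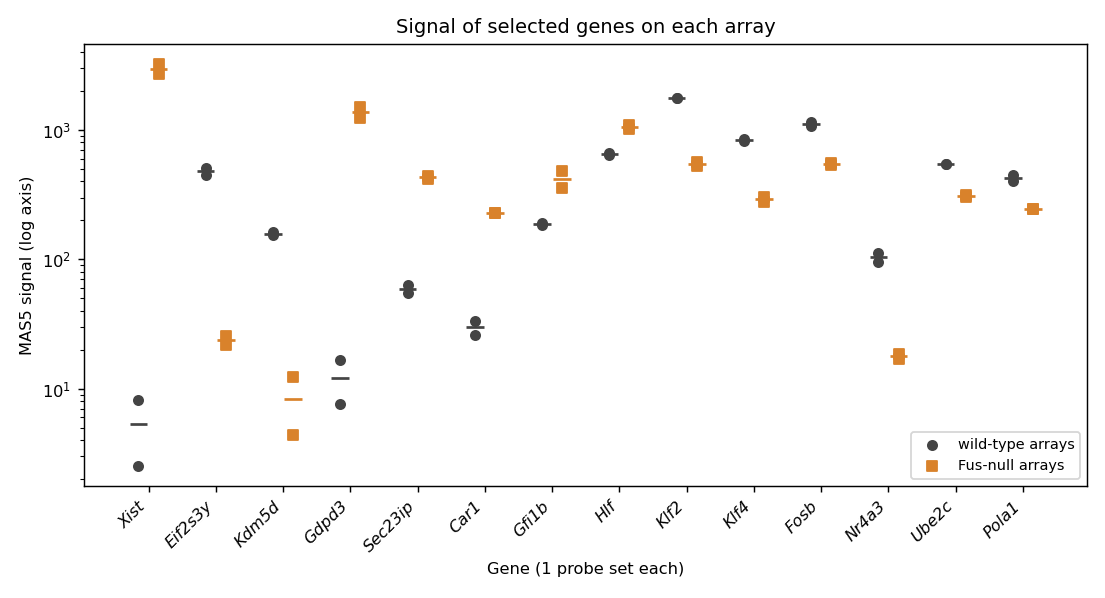
MAS5 signal (log axis) of 14 genes, picked after their values were seen, on each array, with circles for the 2 wild-type arrays, squares for the 2 Fus-null arrays and lines for the group means. The arrays of the genotypes do not overlap for any of these genes: Klf2 lay at 1771 and 1765 on the wild-type arrays and at 522 and 566 on the Fus-null arrays.

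Of the genes fixed for naming, the relatives of Fus in the FET family gave no call. Ewsr1 had log2 differences of 0.05 and -0.10 at its 2 tested probe sets, and Taf15 had 0.39 (SE 0.24). Kit, the receptor used in the KSL gate, had a signal of 1165 ± 104 in wild-type and 973 ± 232 in Fus-null cells at its brightest probe set (log2 difference -0.28, SE 0.17, adjusted p = 0.475 by limma). Mecom, a transcription factor of stem cells, had a log2 difference of -0.40 (SE 0.13, adjusted p = 0.226). Cdkn1a, the inhibitor p21 of cyclin-dependent kinases, fell at 1 probe set, from 265 ± 28.2 to 123 ± 8.93 (adjusted p = 0.0167, but 0.0531 without wild-type replicate 2), and its brighter probe set had a log2 difference of -0.86 that did not pass (adjusted p = 0.0918). The Fus and Ly6a transcripts were not analysed here by name.

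At least 2-fold differences in all 4 pairs of arrays were seen at 160 probe sets, 77 higher and 83 lower in Fus-null cells. The other 2 splits of the arrays gave 25 and 36, but there the genotype difference works against agreement of the pairs. In the simulation, where the noise was equally wide in both groups, 62 unchanged probe sets met the rule. On chromosome 7, 7 neighbours of Fus met this rule, with places counted in protein-coding genes from Fus. Slx1b, a subunit of a structure-specific endonuclease, lay at place -71 and fell from 33.7 ± 1.43 to 0.912 ± 1.08, a call lost with no filter, while its other probe set had a log2 difference of -0.68 that did not pass. Gdpd3, a phosphodiesterase of lipids, lay at place -67 and rose from 12.1 ± 6.35 to 1368 ± 172 (log2 difference 6.68, SE 0.28). Sec23ip, a protein of the secretory pathway, lay at place 17 and rose from 59.3 ± 5.99 to 430.3 ± 17.5, but its other probe set had a log2 difference of -0.49 that did not pass. Wdr11 at place 19 fell from 503 ± 41.6 to 182 ± 15.4, and 9130023H24Rik at place 7 from 69.5 ± 4.47 to 27.4 ± 3.39, the latter not with no filter or without either wild-type array. Tmem219 at place -56 and Slc5a2, a glucose transporter gene, at place 10 were higher by 1.28 and 1.57 and did not pass limma's threshold (adjusted p = 0.121 and 0.147). Brighter probe sets of these 2 genes had log2 differences of -0.11 and -0.09 and did not pass either. Within 100 places of Fus, 7 of 142 tested genes met the rule (4.93%), against 88 of 11723 other autosomal genes (0.751%). The one-sided Fisher exact p was 0.000139, in a test chosen after this gathering was seen. The fixed list of genes near Fus had 29 of 51 members higher, with Gdpd3 as its single call, and did not pass as a whole (camera adjusted p = 0.413), although it passed as higher without wild-type replicate 1 (adjusted p = 0.0208). Its next members by size, Taok2 and Sephs2, had log2 differences of 0.74 and 0.63.

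**Figure D3:**
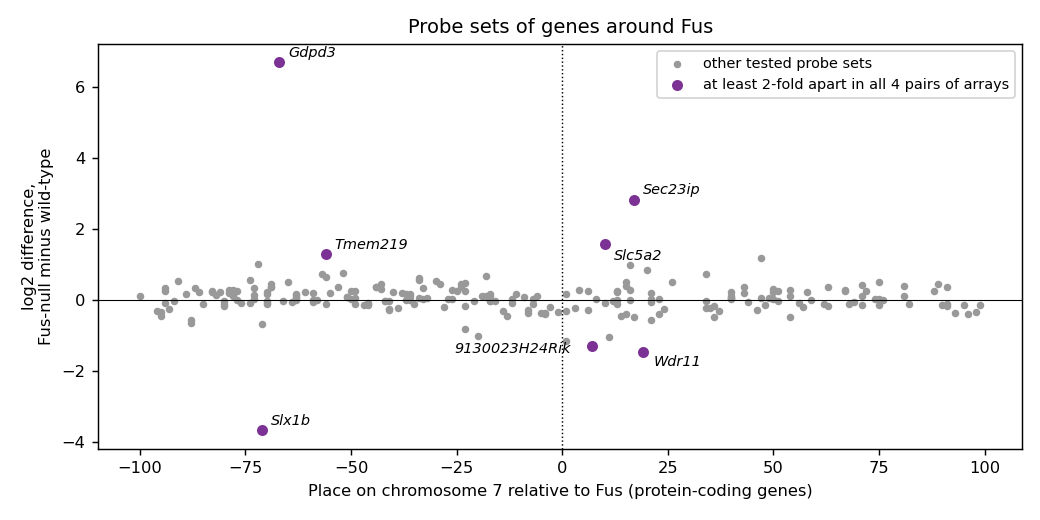
Log2 difference between Fus-null and wild-type arrays (vertical axis) of the tested probe sets of genes within 100 protein-coding genes of Fus on chromosome 7, by place from Fus (horizontal axis, dotted line at Fus). Purple points are the 7 probe sets at least 2-fold apart in all 4 pairs of arrays, which lay on both sides of Fus.

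Among gene lists, 6 were higher and 6 lower in Fus-null cells by camera at the preset correlation. None of these calls was kept with an estimated correlation, where the lists' adjusted p ran from 0.308 to 0.689. In that setting camera rests on the 2 residual degrees of freedom, so a list can hardly pass. The estimate lay below the preset value for the mitosis (-0.0198), quiescence, break repair, cholesterol and histone lists. It lay above that value for the other called lists, up to 0.722 for ribosomal protein genes. These losses therefore cannot decide whether correlation between genes produced the calls. By fry, which tests whether a list's genes move one way on balance, 1 list was called, the mitosis list (adjusted p = 0.00334).

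Mitosis genes were lower almost without exception. Of 48 tested members 47 were lower, with a median log2 difference of -0.33 (camera adjusted p = 7.43e-15, and adjusted p = 0.308 with an estimated correlation). Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, fell from 543 ± 1.04 to 311 ± 7.87 and was the single member past the threshold over all genes, which it did not pass with median scaling or without either wild-type array. Adjusted over the list alone, 21 fell, among them Birc5, the survivin subunit of the chromosomal passenger complex (log2 difference -0.73), and the centrosomal kinase gene Nek2 (-0.61). The median was -0.33 on the first and -0.36 on the second Fus-null array.

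Genes of DNA replication and repair were also lower as lists. Of 50 S-phase genes 36 were lower (camera adjusted p = 0.000252, and adjusted p = 0.319 with an estimated correlation). Pola1, the catalytic subunit of DNA polymerase alpha and X-linked, fell from 428 ± 34.4 to 246 ± 0.948, and adjusted over the list alone the thymidine kinase gene Tk1 and Dtl, a factor of licensing control, fell too. Of 47 genes of double-strand break repair 38 were lower (camera adjusted p = 0.00118, and adjusted p = 0.319 with an estimated correlation), with 0 calls by limma over all genes or adjusted over the list alone and 1 higher and 12 lower at an unadjusted p under 0.05. Fancd2 of the Fanconi pathway had -1.02, Bard1 -1.13 and Lig4 0.95, none of which passed. Histone genes were lower for 8 of 10 members (camera adjusted p = 0.00404, and adjusted p = 0.319 with an estimated correlation), and H2bc21 and H2aw fell, with log2 differences of -0.87 and -0.83, by both adjustments. H2bc21 and H2aw did not pass over all genes with median scaling or without wild-type replicate 2, nor H2aw without wild-type replicate 1, nor H2bc21 with no filter or without X, Y and unnamed probe sets. H2bc22 had -0.55 and did not pass. The histone list did not pass without Fus-null replicate 1 (adjusted p = 0.205, range over its alternatives 4.71e-05 to 0.319).

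Immediate-early genes were lower for 18 of 25 members, with a median log2 difference of -0.40 (camera adjusted p = 5.48e-07, and adjusted p = 0.319 with an estimated correlation). Past the threshold over all genes were Klf2, Klf4, a Krüppel-like factor that fell from 832 ± 21.5 to 291 ± 18.8, the zinc-finger factor Egr3, which fell from 186 ± 13.9 to 89.9 ± 13.5, and, named after their values were seen, Atf3, Fosb and Klf6. Egr3 did not pass with no filter, with median scaling or without wild-type replicate 2, and Fosb and the 4 called probe sets of Klf6 did not pass without wild-type replicate 1. Adjusted over the list alone, 12 fell and 1 rose. The median was -0.38 on the first and -0.42 on the second Fus-null array. The list of quiescence genes and inhibitors of cyclin-dependent kinases was lower for 13 of 17 members (camera adjusted p = 0.00404, and adjusted p = 0.319 with an estimated correlation). Its call over all genes, Nr4a2, is an immediate-early nuclear receptor and fell from 617 ± 46.3 to 262 ± 40.9. Adjusted over the list alone, 4 fell, Cdkn1a among them, and 1 rose. Foxo3, which restrains stem-cell cycling, had 0.67 with a wide spread in Fus-null cells (592 ± 397).

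Genes of stem cells were higher for 35 of 48 members (camera adjusted p = 0.00404, and adjusted p = 0.319 with an estimated correlation). Gfi1b, a transcriptional repressor found in stem and erythroid cells, rose from 187 ± 5.53 to 419 ± 93.5. Mycn, a Myc-family factor, rose from 265 ± 7.54 to 508 ± 60.6, but neither gene passed with no filter or with median scaling. Hlf, a stem-cell transcription factor named after its values were seen, rose from 653 ± 14.7 to 1054 ± 61.9 with an adjusted p of 0.0499. Adjusted over the list alone, 5 rose, and Ndn had -0.81 and did not pass.

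The erythroid, the granulocyte and monocyte progenitor, and the monocyte, macrophage and dendritic lists were higher by camera at the preset correlation, while the lists of other mature blood cells did not pass in the main fit and the neutrophil list passed as higher in 5 alternative settings. Of 23 erythroid genes 15 were higher (camera adjusted p = 5e-04, and adjusted p = 0.528 with an estimated correlation). Car1, Ermap and, named after its values were seen, Zfpm1, the cofactor of Gata1, rose over all genes, and adjusted over the list alone 8 rose, Epor, the erythropoietin receptor gene, among them with a log2 difference of 1.03. Of 26 granulocyte and monocyte progenitor genes 21 were higher (camera adjusted p = 0.00142, and adjusted p = 0.435 with an estimated correlation). Adjusted over the list alone 9 rose and 2 fell, with Igsf6, an immunoglobulin superfamily gene, at a log2 difference of 1.12, Hp, which encodes haptoglobin, at 55.8 ± 17.7 and 123 ± 2.40 and F13a1, a coagulation factor subunit of monocytes, at 87.0 ± 11.8 and 177 ± 54.1. The single call over all genes went the other way: Csf3r, the G-CSF receptor gene, named after its values were seen, fell from 554 ± 32.8 to 345 ± 20.96. Of 21 monocyte, macrophage and dendritic genes 18 were higher (camera adjusted p = 0.000396, and adjusted p = 0.319 with an estimated correlation). By limma 0 passed over all genes, with 8 higher and 1 lower at an unadjusted p under 0.05, and 5 rose adjusted over the list alone, among them the class II gene H2-Eb1 (140.4 ± 33.0 and 287 ± 57.1) and Cd68 (116 ± 18.5 and 200 ± 14.2). C1qb had a log2 difference of 0.63 and did not pass.

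Ribosomal protein genes were higher for 40 of 42 members (median log2 difference 0.42, camera adjusted p = 8.30e-06, and adjusted p = 0.689 with an estimated correlation), but the median was 0.09 on the first Fus-null array and 0.74 on the second. The second Fus-null array also had the highest ratio of 3' to 5' signal for Actb, 3.49 against 2.08 to 2.40 on the other arrays. The list did not pass under quantile normalization (adjusted p = 0.144) or without Fus-null replicate 2 (adjusted p = 0.0521), with a range over its alternatives of 5.22e-19 to 0.689. The single call in it, Rpl14, fell from 625 ± 13.5 to 318 ± 54.2 but did not pass with no filter, with median scaling or without wild-type replicate 2. Rpl27a had 2.02 with 570.3 ± 679.9 in Fus-null cells, and Rpl12 0.57. Genes of cholesterol synthesis were higher for 16 of 20 members (camera adjusted p = 0.00524, and adjusted p = 0.319 with an estimated correlation). Msmo1, a sterol demethylation enzyme, rose from 99.9 ± 7.67 to 200.3 ± 11.1 but did not pass with median scaling or without wild-type replicate 1, and adjusted over the list alone 4 rose and 1 fell, with Mvd at 1.07 and Tm7sf2 at -0.70.

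**Figure D4:**
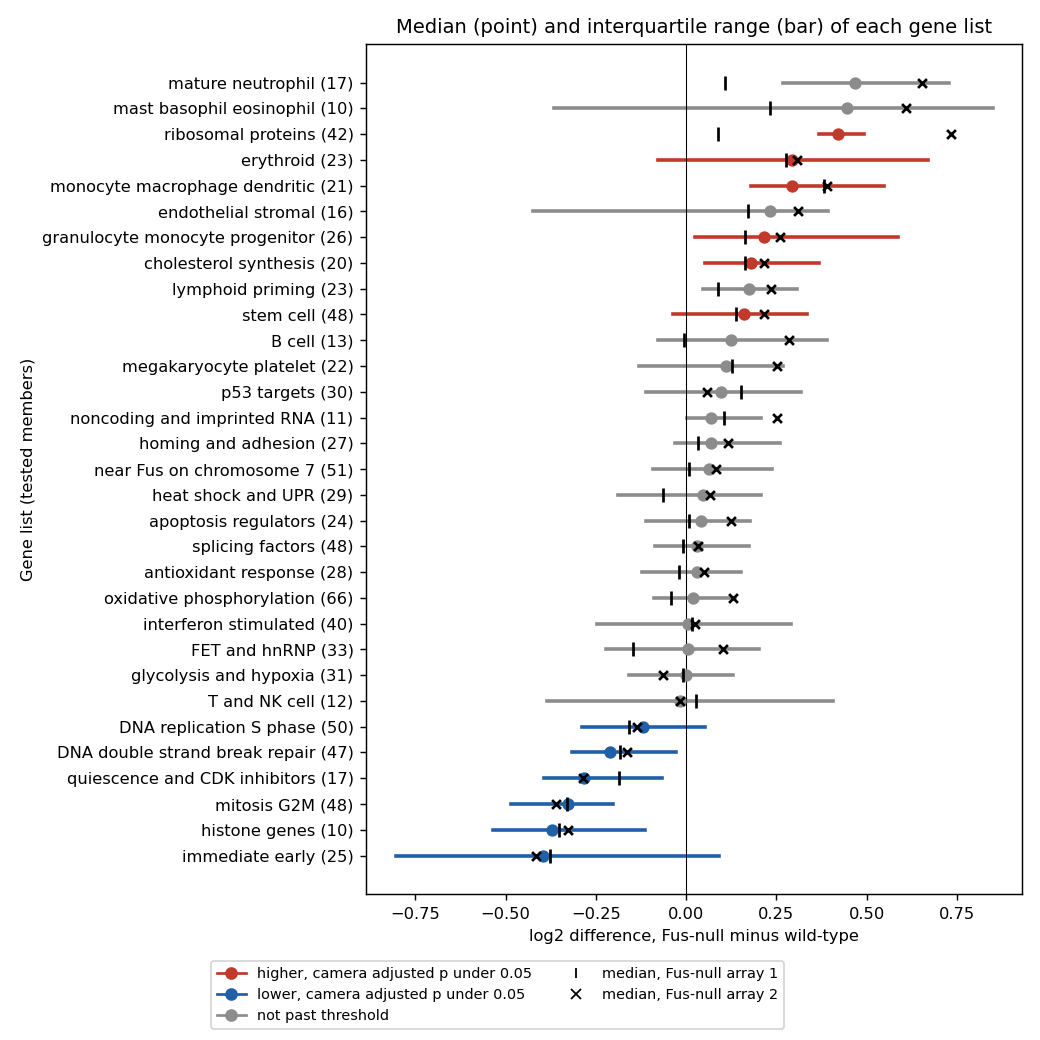
Log2 difference between Fus-null and wild-type arrays (horizontal axis) of the 31 tested gene lists (vertical axis, tested members in parentheses), as the median (point) and interquartile range (bar) over members, with the medians on the first (vertical tick) and second (cross) Fus-null array. Lists in red or blue passed camera at the preset correlation. The 2 medians of the ribosomal protein list lay at 0.09 and 0.74.

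The remaining lists did not pass. Among markers of cells that the KSL gate should remove, neutrophil genes were higher for 14 of 17 members (camera adjusted p = 0.0771), with S100a9 at 96.3 ± 86.7 in wild-type and 173 ± 61.7 in Fus-null cells and log2 differences of 0.96 for Wfdc21 and 0.89 for Chil3. This list passed as higher with no filter (adjusted p = 0.0491), with median scaling (0.00161), with the replicate number as a block (0.0461), without chromosome 7 genes near Fus (0.0489) and without wild-type replicate 1 (median 1.17, adjusted p = 7.96e-15), and had a median of -0.023 without wild-type replicate 2, its adjusted p over the alternatives reaching 0.694. B-cell genes were higher for 8 of 13 members (adjusted p = 0.695), T and NK genes for 6 of 12 (0.902), mast, basophil and eosinophil genes for 6 of 10 (0.456), megakaryocyte and platelet genes for 14 of 22 (0.248), and endothelial and stromal genes for 11 of 16 (0.359), a list that passed as higher with the filter at the 60th percentile (adjusted p = 0.0361). Lymphoid priming genes were higher for 19 of 23 (0.0942), with Ccr9 as the single call and Rag2 at -1.85 and Ccr7 at 1.39. After adjustment within the list, 3 mast, basophil and eosinophil genes rose and 2 fell, with log2 differences of 1.72 for Prg2, 1.66 for Cma1 and -1.01 for Gzmb, and 2 megakaryocyte and platelet genes rose, Gp5 among them with 0.59, beside Clec1b with 0.90 and Gp1bb with 0.56, which did not pass. In the neutrophil, B-cell, T and NK, and endothelial and stromal lists 0 members passed over all genes or over the list alone. The largest log2 differences were 1.78 for Igll1, 1.03 for Vpreb3 and -0.97 for Fcmr among B-cell genes, -1.04 for Zap70, 0.89 for Il2rb and -0.78 for Cd28 among T and NK genes, and 0.99 for Cxcl12, -0.99 for Acta2 and 0.77 for Fabp4 among endothelial and stromal genes.

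Among lists of processes linked with Fus, that of double-strand break repair was lower by camera at the preset correlation, as given above. Its members gave 0 calls by limma, and the other lists did not pass by camera in the main fit. Genes of FET proteins and hnRNPs were higher for 17 of 33 members (camera adjusted p = 0.342) and splicing factors for 28 of 48 (0.959). By limma 0 members of either passed over all genes or adjusted over the list alone, and at an unadjusted p under 0.05 the first had 4 lower and the second 1 higher and 4 lower. The largest log2 differences of the first were those of Hnrnpl (-0.49) and Hnrnpu, a nuclear matrix RNA-binding protein (-0.48), and those of the second Snrpd3 (-0.43), Srrm2, a spliceosomal scaffold (0.38), and Ddx17 (0.36). The FET and hnRNP list passed as lower under quantile normalization (adjusted p = 0.0231) and without Fus-null replicate 2 (adjusted p = 0.00839), with a range over its alternatives up to 0.734. Targets of p53 were higher for 21 of 30 members (0.456). Adjusted over the list alone, Eda2r and Sesn2 rose, by 1.66 and 1.03, and 3 fell, Cdkn1a among them.

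Heat-shock and unfolded-protein genes were higher for 15 of 29 (camera adjusted p = 0.509), while the inducible chaperones Hspa1a and Hspa1b fell, with log2 differences of -1.58 and -1.46 at the brightest probe set of each, which did not pass with no filter. These 2 also fell adjusted over the list alone, and Asns, the asparagine synthetase gene, rose (0.69). Interferon-stimulated genes were higher for 21 of 40 (0.959), and Ifit2 fell from 192 ± 5.20 to 112 ± 1.78. Within that list, 2 fell, Ifih1 (-0.71) among them, and 2 rose, Iigp1 (0.69) among them, by adjustment over the list alone. Apoptosis regulators were higher for 13 of 24 (0.902), and Bcl2l11, the gene of the BH3-only protein Bim, fell adjusted over the list alone, while Bmf had 0.79 and Pmaip1 -0.63 and did not pass. Oxidative phosphorylation genes were higher for 36 of 66 (0.530) and passed as lower without Fus-null replicate 2 (median -0.042, adjusted p = 0.00858). Glycolysis and hypoxia genes were higher for 16 of 31 (0.509), antioxidant genes for 15 of 28 (0.902), homing and adhesion genes for 15 of 27 (0.265), and noncoding and imprinted RNAs for 8 of 11 (0.536). By adjustment within each list, 1 oxidative phosphorylation gene, Ndufb2 (-0.56), and the hypoxia genes Vegfa (-0.99) and Pdk1 (-0.56) fell, and 2 antioxidant genes rose, Txnip (0.67) among them. Further members with large log2 differences that did not pass were Ndufa7 (-0.51), Sdhc (-0.45), Ankrd37 (-0.40), Nqo1 (-0.76), Gsta4 (-0.55), the adhesion genes Itga5 (0.88), Vcam1 (0.44) and Esam (0.42), and the noncoding RNAs Mirg (0.84), Snhg8 (0.35) and Neat1 (-0.31). Camera compares a list with all other genes, and it read the splicing, interferon, FET and hnRNP, heat-shock, oxidative phosphorylation and glycolysis lists as lower although their medians lay at or slightly above 0.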

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

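The test of the mature-cell lists, the test of escape genes and the test of second probe sets were written before their results were seen, and the other tests in this part were chosen after the result was seen.

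The hybridization spike-ins, control transcripts added at fixed amounts before hybridization, were not part of the comparison. On the second Fus-null array their 9 probe sets had a median ratio of 2.18 to the wild-type mean, against 1.08, 0.924 and 1.06 on the other arrays. This array also had a 3' to 5' ratio of 3.49 for Actb and 2.65 for Gapdh.

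The immediate-early genes were lower in the Fus-null arrays, and the array with high spike-in signal may be thought to carry this. The first Fus-null array alone gave a median of -0.378 (bootstrap interval over genes -0.586 to -0.207, 25 genes), which argues against it. The intervals in this part resample genes or probe sets and carry no spread between arrays. Fewer mature cells in the Fus-null samples were tested with the members above a signal of 20 of 4 lists of mature cells, and monocyte genes had a median of 0.293 (interval 0.180 to 0.591, 17 genes), which argues against a loss of those cells. The neutrophil median of 0.514 (12 genes) decides nothing, since the median of the whole list was -0.023 without wild-type replicate 2, and those of B-cell genes, 0.123 (interval -0.960 to 0.391, 5 genes), and of T and NK genes, -0.226 (interval -0.785 to 0.330, 7 genes; -0.0159 over all 12 tested members), leave a loss of lymphocytes open. Handling that differed between the genotypes before lysis could also induce such genes in 1 group. Inducible heat-shock genes had a median of -0.0935 (interval -1.52 to 0.219, 6 genes), with only Hspa1a and Hspa1b past the threshold, so handling and loss of Fus cannot be told apart from these arrays.

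Xist and the Y-linked genes separated the genotypes. Xist raised by loss of Fus in cells of one sex would leave Y-linked genes in place, and their median of -4.07 argues against it. Donor cells of different sex predict that genes escaping X inactivation are higher with Xist, and their median was 0.257 (range -0.191 to 0.370), with 3 of 5 genes higher. Xist lay at 5.38 ± 4.02 in wild-type and 2957 ± 379 in Fus-null cells, and Eif2s3y at 480.4 ± 44.4 and 23.7 ± 2.62. With the same split on every array, these values argue against cells of one sex in both groups. Sex and genotype therefore ran together in all 4 arrays, and an effect of sex on the other differences stays open.

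Genes that met the 2-fold rule gathered near Fus on chromosome 7. Against other autosomal genes, the one-sided Fisher exact p was 0.000139 for genes within 100 places. It was 0.0032 for genes 11 to 100 places away (5 of 127) and 0.00572 for those 1 to 10 places away (2 of 15). These tests were chosen after the gathering was seen in the same genes, so they cannot exclude chance placement. Nor can they settle how far from Fus an effect would reach. The list of genes near Fus that was fixed beforehand did not pass (camera adjusted p = 0.413). A strain-derived segment carried along with the disrupted gene is a candidate explanation, and it could act on transcript levels or only on probe binding. The other probe sets of these genes, signed by the first, had a median of -0.0866 (interval -0.489 to 0.684, 5 probe sets), too wide to tell which. No test separated such a segment from an effect of Fus loss on these genes.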

How the results depend on the processing

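The alternatives without the X and Y chromosomes and unnamed probe sets, without chromosome 7 genes near Fus, and with the pseudocount at the 75th percentile were chosen after the data were seen, and the others before. No called gene or list named in the report reversed under any alternative. The alternatives for the Fus transcript gave no value, since no probe set is named Fus.

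The 172 calls by limma became 78 with no filter, 105 with median scaling (25 higher, 80 lower), 14 without the intensity trend, and 106 without X, Y and unnamed probe sets; leaving out 1 array gave 83 to 4226. With no filter more probe sets are tested; the cause was not tested for the other settings. All 172 were among the calls without Fus-null replicate 1 and among those without Fus-null replicate 2, while 86 and 75 were shared without wild-type replicate 1 and 2. Median scaling also moved the median log2 difference of all tested probe sets from 0.036 to -0.093, against which its differences are to be read. The 160 probe sets of the 2-fold rule became 63 and 26 with the pseudocount at the 50th and 75th percentile, 508 with no filter, 64 with the filter at the 60th percentile, 105 without X, Y and unnamed probe sets, and 441 to 1043 without 1 array, where fewer pairs have to agree. A larger pseudocount shrinks the differences of dim probe sets by construction, so signal near background limits this count. The 12 lists became 0 with an estimated correlation and 1 with fry, and were 11 to 14 under the other settings.

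Of 75 probe sets past the threshold whose genes are named in these texts, each kept its direction under every alternative that tested it. A probe set that passed has groups well apart, so a kept direction adds little. Without the intensity trend 68 did not pass (adjusted p by limma 0.0769 to 0.307), all but those of Xist, Eif2s3y, Gdpd3, Gpr4 and Sec23ip. With no filter 33 did not pass (0.052 to 0.128): 9130023H24Rik, Ccr9, Csf3r, Egr3, Eps8l1 at both probe sets, Ermap, Fosl1, Gfi1b, Gm10451, H2bc21, Hlf, Hspa1a, Hspa1b at 1 probe set, Ifit2, Igkv9-120, Klf6 at 2, Klf9, Klf11, Mn1, Mycn, Nfkbia, Nfkbiz at 1, Nr4a2 at 1, Pde3b, Pde4b at 1, Pola1, Rbmx, Rpl14, Slx1b, Tnfaip3 and Zfpm1. With median scaling 21 did not pass (0.0557 to 0.217): Csf3r, Egr3, Fcer1g, Gfi1b, H2aw, H2bc21, Hlf, Ifit2, Klf6 at 1, Klf9, Klf11, Mn1, Msmo1, Mycn, Nr4a2 at 1, Ogt, Pim2, Pola1, Rpl14, Ube2c and Zfpm1. Without wild-type replicate 1 or 2, 32 and 31 did not pass (0.0504 to 0.341), 24 of them in both cases, among them Csf3r, Fosl1, H2aw, Hlf, Ifit2, Pola1, Ube2c and Zfpm1; Ccr9, Ermap, Fosb, H3c11, Msmo1 and Tnfaip3 did not pass without replicate 1 alone, and Cdkn1a, Egr3, H2bc21, Mycn, Pde3b, Ptgs2 and Rpl14 without replicate 2 alone. Csf3r and Hlf also did not pass with the pseudocount at the 5th percentile, Ifit2 and 1 probe set of Nr4a2 under quantile normalization, Hlf and 1 probe set of Nfkbiz with the block, Csf3r, H2bc21, Hlf, Hspa1a, Tnfaip3 and 1 probe set of Nr4a2 without X, Y and unnamed probe sets (0.0503 to 0.0543), and Csf3r and Hlf without chromosome 7 genes near Fus (0.0523 each). The cause was not tested beyond the fewer arrays or larger number of tests that some settings bring.

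The correlation of the deviations of same-numbered arrays was -0.0458, so the replicate numbers share only a number. With the replicate number as a block, 247 probe sets passed, 169 of them among the 172, with 238 probe sets by the 2-fold rule within pairs and 13 lists.

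Reversals concerned values that had not passed, and their cause was not tested. By camera's direction, with medians given, apoptosis regulators reversed with no filter and without probe sets marked _x_at or _s_at (0.034 each), with median scaling (-0.093) and with the mean of all probe sets of a gene (-0.00055); interferon genes with cyclic loess (0.0093), no intensity trend and fry (0.0051 each) and the mean (0.017); antioxidant genes with median scaling (-0.10) and the mean (-0.013); T and NK genes with median scaling (-0.14) and the mean (0.14); and splicing factors with fry (0.030). Ewsr1 had -0.081 with median scaling. Without 1 array, at least 1 reversal was seen in list medians that ran from 0.0068 to 0.125 for apoptosis, -0.025 to 0.040 for interferon, -0.023 to 1.17 for neutrophil, -0.019 to 0.050 for antioxidant, -0.15 to 0.10 for FET and hnRNP, -0.0088 to 0.040 for splicing, -0.042 to 0.13 for oxidative phosphorylation, -0.0063 to 0.28 for B-cell and -0.027 to 0.028 for T and NK genes. Likewise single genes ran from -1.41 to 0.31 (H2bc22), -0.088 to 0.19 and -0.32 to 0.12 (Ewsr1), -0.072 to 1.41 (Foxo3), -2.005 to 0.035 (Acta2) and -0.14 to 1.40 (Sephs2).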

Other observations

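The genes in this part were chosen after their values were seen, and no further list was tested for them. They are reported as single genes, not as a group. Nfkbid, an atypical IκB, fell from 1266 ± 81.6 in wild-type to 541 ± 8.84 in Fus-null cells (SD, n = 2 each), and the deubiquitinase gene Tnfaip3 from 1639 ± 120.5 to 759 ± 195. Nfkbiz passed at 2 of 3 probe sets, with log2 differences of -1.13 and -0.90. Nfkbia passed at 1 of its 5 probe sets, with -0.89, while its brightest had -0.14. Tnfaip3, Nfkbia and the second of these Nfkbiz probe sets did not pass with no filter or without wild-type replicate 1. Without wild-type replicate 2, Nfkbia, that Nfkbiz probe set and Ptgs2, named below, did not pass. The chemokine gene Cxcl2 fell from 1076 ± 45.9 to 417 ± 34.6, Ptgs2, the inducible cyclooxygenase gene, from 362 ± 28.2 to 185 ± 1.14, and Il10 from 104 ± 0.718 to 34.4 ± 1.29.

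The phosphodiesterase gene Pde4b, whose product degrades cyclic AMP, passed at 2 of 3 probe sets (log2 differences -1.01 and -0.88), and Pde3b fell from 314 ± 49.0 to 155 ± 1.91. The hexokinase gene Hk3 passed at both probe sets (-0.98 and -0.91). The Krüppel-like factors Klf9, at 1 probe set, and Klf11 passed with a log2 difference of -0.79 each. Among the rises were Mn1, a transcriptional coregulator linked with myeloid leukemia (139.7 ± 2.34 and 256 ± 17.04), and the X-linked genes Ogt, an O-GlcNAc transferase (log2 difference 0.97), and Pim2, a survival kinase (0.87). The calls of Klf9, Klf11 and Mn1 were lost with no filter, with median scaling and without either wild-type array. Those of Ogt and Pim2 were lost with median scaling and without either wild-type array. The second of these Pde4b probe sets was lost with no filter and without either wild-type array, and that of Hk3 without either wild-type array. Pde3b was lost with no filter and without wild-type replicate 2. Without the intensity trend no gene of this part passed.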
